A study of Mus musculus with 4 samples.

How the data were processed

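The samples were macrophages grown from mouse bone marrow, labelled wild type (WT) or knockout for OGT, the enzyme that attaches O-linked N-acetylglucosamine to nuclear and cytoplasmic proteins. Per the labels, bone marrow cells were cultured for 7 days with 20 ng/mL of M-CSF, the growth factor that drives macrophage differentiation. IL-4 at 20 ng/mL for 24 h was then used to polarise the cells, and libraries were built from 1 µg of total RNA with a SMARTer mRNA-seq kit. The 0 h samples carry the same treatment tag as the 24 h ones and were read as cells without IL-4 from their time. STAR and StringTie are named for GRCm38 in the submitters' processing notes. The strandedness of the libraries, the annotation release used by the authors and the part of Ogt that was deleted are not given in the sources used here.

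The authors' values are FPKM, fragment counts scaled to transcript length and library size, for 52550 Ensembl genes in 4 libraries. The table names no unit, so FPKM was read from the values: the column totals differ between libraries, from 338704 to 353093, which excludes TPM. No raw counts were used. Depth was estimated from longer genes with 1 exon. Their most common product of value and exon length, sought within a preset range, was taken to stand for 1 fragment. This gives an estimate of 40.0 to 43.8 fragments for a transcript of 2 kb at 1 FPKM, and the preset range bounds it. The depth itself is not stated, and these are estimates from the values, not counts.

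Gene symbols, types and positions were taken from GENCODE M21 (GRCm38), with positions counted from 1. A symbol was found for 52403 genes, and the other 147 kept their identifier. Genes sharing a symbol were summed, which left 52476 names. In these symbols, Oga, the enzyme that removes O-linked N-acetylglucosamine, is Mgea5.

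The choices that follow were made before the data were examined. The measure of a difference was the log2 ratio of FPKM + 1, so a pseudocount of 1 was added to both values. This scale understates differences of genes near or under 1 FPKM. A gene was kept for a comparison if it reached 1 FPKM in at least 1 of its libraries. Kept genes with a log2 difference of at least 1 (2-fold) are counted as higher or lower. The 5 comparisons were the IL-4 response in WT, the IL-4 response in the knockout, the knockout against WT at 0 h and at 24 h, and the knockout response minus the WT response. With 1 library per group there is no error between replicates to test against. A fit of genotype and time without their interaction was not run. No p-value is given and every count is a description of these libraries.

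Fixed gene lists (32) and marker lists of other cell types (12) were each described by the median log2 difference of their kept members, where at least 5 were kept. Each median was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile given is the percent of random lists with a lower median, and a list outside the 2.5 to 97.5 range is said to stand apart. Ogt was left out of its own list between genotypes. Correlations between comparisons were computed across genes, which are not independent replicates, and only for pairs of comparisons with no library in common.

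The genes named are Ogt, Mgea5, Arg1, Retnla, Chil3 and Mrc1, then in each comparison the 10 largest differences in each direction among genes at 5 FPKM or more in at least 1 library. Predicted genes, antigen receptor segments and small RNAs were left out of that choice. Up to 4 members of each list past 2-fold were added. Other genes named are said to have been chosen after their values were seen, or are given without a verb of change. Exons of 47 of the 184 genes so chosen overlap exons of another annotated gene, among them Mgea5, Apoc2, Pet117, Pnp2, B3gnt2, Golph3l, Map2k7, Clmp, Itgam, Tgm2, Fn1, Il4i1, Zbtb22 and Zfx. Their values are less certain. The same holds for near-identical copies such as Eno1 and Eno1b, Ifit3 and Ifit3b, Lyz1 and Lyz2, Pnp and Pnp2, and Hist2h2aa1.

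In a simulation built on the WT 0 h values of 11168 genes, the procedure found 50 of 50 genes set 4-fold higher and 43 of 50 set 4-fold lower. It found 10 of 50 genes set 2-fold higher and 3 of 50 set 2-fold lower. The pseudocount pulls ratios toward 0, and a change set at the cut itself can fall on either side of it through noise. None of the other 10946 genes, which include 30 set higher by less than 2-fold, passed 2-fold. Of 100 random lists with no change, 7 fell outside the central range. The simulation holds counting noise, with the same fragments per FPKM for every gene, and no variation between cultures. An unchanged gene could therefore hardly pass 2-fold in it. Its lists held genes with independent noise, so the 7 of 100 does not carry over to lists whose members vary together between cultures.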

Results

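Gene expression was measured by RNA-seq in bone marrow-derived macrophages of 2 genotypes, WT and OGT knockout, without IL-4 (0 h) and after 24 h of IL-4. Each of the 4 groups held 1 library, so there are no replicates and no difference here can be set against the variation between cultures. No culture kept for 24 h without IL-4 is labelled. The response to IL-4 here means 24 h against 0 h, and cannot be separated from an effect of time in culture. The FPKM totals were 338704 for WT at 0 h, 352793 for WT at 24 h, 339946 for the knockout at 0 h and 353093 for the knockout at 24 h. Genes at 1 FPKM or more numbered 11169, 10978, 10994 and 10920, in the same order. Mitochondrially encoded genes took 5.87% of the total in WT and 6.93% in the knockout at 0 h, and 8.67% and 8.64% at 24 h. Ribosomal protein genes took 4.69% and 4.2% at 0 h, and 5.03% and 4.24% at 24 h. The 10 highest genes held between 18.2% and 20.6% of each library.

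Ogt itself (ENSMUSG00000034160, chromosome X, 101640060 to 101684351, + strand) was measured at 27.4 FPKM in WT at 0 h, 29.8 in WT at 24 h, 14.2 in the knockout at 0 h and 14.5 in the knockout at 24 h. The knockout thus held 51.8% of the WT value at 0 h (log2 difference −0.90) and 48.5% at 24 h (−0.99). Transcripts of Mgea5 (ENSMUSG00000025220, chromosome 19, 45750259 to 45783837, − strand), which encodes the opposing enzyme OGA, were also lower in the knockout. They stood at 31.4 FPKM in WT against 14.9 in the knockout at 0 h (log2 −1.03), and at 23.4 against 10.6 at 24 h (−1.08). No other measured member of the O-GlcNAc and hexosamine list reached 2-fold between genotypes at either time. Its nearest members were Nagk at 0 h (−0.44) and, at 24 h, Amdhd2 (0.80) and Eogt (−0.53). The gene-level values of Ogt cover all of its exons, so a transcript lacking the deleted part would still be counted. They do not establish how much OGT was lost, and neither incomplete deletion nor a remaining intact allele is excluded by them. With the libraries rescaled, Mgea5 at 0 h came to −0.96, just under 2-fold.

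**Figure D1:**
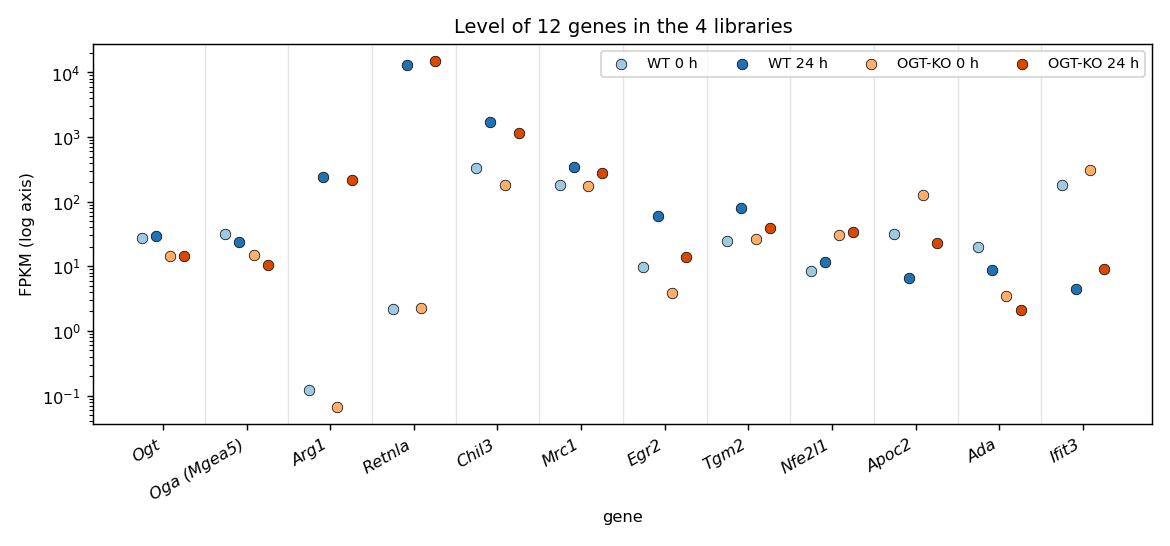
FPKM of 12 genes (horizontal axis) in the 4 libraries on a log axis, with 1 point per library and no replicates. Ogt lies at 14.2 and 14.5 in the knockout libraries against 27.4 and 29.8 in WT, while Arg1 lies at 0.12 (WT) and 0.07 (knockout) at 0 h and at 240.4 and 219 at 24 h.

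The first comparison asked how WT macrophages differed after 24 h of IL-4. Well-known IL-4 target genes were among the largest positive differences. Retnla, which encodes a secreted resistin-like protein (chromosome 16, 48842551 to 48844461, + strand), went from 2.17 to 12961 FPKM (4086-fold on the scale of FPKM + 1). Arg1, the arginase that turns arginine into ornithine (chromosome 10, 24915221 to 24927484, − strand), went from 0.12 to 240.4 (7.75). The lectin gene Mgl2 went from 5.06 to 264 (5.45), Pdcd1lg2, which encodes the PD-1 ligand PD-L2, from 0.11 to 42.4 (5.29), and Chil3, which encodes a chitinase-like protein, from 334 to 1738 (2.38). The mannose receptor gene Mrc1 differed by less than 2-fold, at 182 and 341 FPKM (0.90). Rnase2a was listed at 0 without IL-4 and at 358 FPKM with it. Eno1b, a copy of an enolase gene, was listed at 0 and then at 37.0. The amino acid oxidase gene Il4i1 (5.37), Tmem26 (5.24), the cell fusion gene Ocstamp (4.49) and the VEGF receptor gene Flt1 (4.34) were also among the largest differences.

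In the list of IL-4-induced genes, 24 of 28 measured members were at least 2-fold higher in WT and none was 2-fold lower (median log2 2.76, percentile 100). Genes for handling new proteins and for energy metabolism were higher as groups. Of 20 unfolded protein response genes, 8 passed 2-fold (median 0.87, percentile 100), led by Pdia4 (2.06) and Sdf2l1 (2.03). Of 38 nuclear-encoded oxidative phosphorylation genes, 37 had positive differences and 10 passed 2-fold (0.70, percentile 100), among them Atp5b (1.52) and Cyc1 (1.44). All 13 mitochondrially encoded genes had positive differences (0.69, percentile 99.7), as did 34 of 35 cell cycle genes (0.45, percentile 100), with the replication genes Pcna (1.52) and Mcm5 (1.35) past 2-fold. MHC class II genes were higher in 6 of 10 cases (1.17, percentile 100), including H2-DMa (1.74) and the class II transactivator Ciita (1.34). Genes of osteoclasts and fused macrophages had a median of 0.89 (percentile 99.98), with Dcstamp at 2.07 and then 37.6 FPKM (3.65).

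Interferon and inflammatory genes were lower at 24 h of IL-4 than at 0 h in WT. All 35 measured interferon-stimulated genes had negative differences and 30 passed 2-fold (median −1.68, percentile 0), with Ifit3 at 180.2 and then 4.43 FPKM (−5.06) and Ifit2 at 90.4 and then 5.35 (−3.85). Of 25 NF-kB genes, 10 were 2-fold lower (−0.97, percentile 0), led by Nfkbiz (−3.56) and Lcn2 (−2.37). In the Toll-like receptor list 6 of 20 members were lower, including the LPS co-receptor gene Cd14 (−3.63) and Tlr9 (−2.33). Scavenger receptors were lower in 8 of 20 cases, with Marco at −3.38 and Clec4n at −3.17. The macrophage identity list was lower in 8 of 22 members (−0.31, percentile 0.21), among them Maf (−2.37) and Lyz2 (−1.84). Markers of neutrophils (8 of 11 lower, −1.59) and monocytes (5 of 9 lower, −1.41) were lower in the same comparison. The formyl peptide receptor genes Fpr1 (−4.30) and Fpr2 (−3.75), Ms4a6b (−4.58), Adgre4 (−4.41) and Siglece (−3.71) were among the largest negative differences. In all, 556 genes were higher and 732 lower among 11687. A pseudocount of 5 gave 253 and 304 genes, and 24 of the 112 genes past 2-fold that were named by rule came under it.

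The next comparison gave the IL-4 response of the knockout. Retnla went from 2.23 to 14904 FPKM (12.17), Arg1 from 0.07 to 219 (7.69), Mgl2 from 2.86 to 222 (5.85) and Chil3 from 182 to 1164 (2.67). Mrc1 was at 174 and 282 (0.69). Rnase2a reached 461 FPKM from 0.10 (8.71), Il4i1 78.7 from 0.26 (5.98), and Dcstamp 58.3 from 1.17 (4.77). Fn1, which encodes fibronectin, stood at 189 after 7.58 (4.47). Of 29 measured IL-4-induced genes, 24 were 2-fold higher and none lower (median 2.92, percentile 100), and 23 were 2-fold higher in both genotypes. Interferon-stimulated genes were lower in 34 of 35 cases (−1.93, percentile 0), with Ifit3 at −4.94, Ifit2 at −4.30 and Rsad2 at −3.53. MHC class II genes (6 of 10 higher, 1.19), unfolded protein response genes (9 of 20, 0.89) and oxidative phosphorylation genes (8 of 38, 0.67) all lay at percentile 100. Cholesterol synthesis genes were 2-fold higher in 5 of 23 cases and positive in 23 (0.68, percentile 99.99), with Cyp51 and Nsdhl at 1.14 each. Members of this list also passed 2-fold in WT, namely Idi1 (1.14), Cyp51 (1.12) and Sqle (1.08). Neutrophil markers had a median of −1.52 and monocyte markers of −1.24, both at percentile 0.

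In the knockout 597 genes were higher and 693 lower among 11577. Of the genes past 2-fold, 424 were higher in both genotypes and 497 lower in both, where independent choices of the same size would share 27.7 and 42.3. Across 12000 genes the responses had a Pearson r of 0.859, a Spearman rho of 0.819 and a slope of 0.885. Of the 1288 genes past 2-fold in WT, 1227 (95.3%) had the same sign in the knockout, and 14 genes passed 2-fold in opposite directions. Under a pseudocount of 5 the knockout counts were 272 and 320, and 25 of 114 genes named by rule came under 2-fold.

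**Figure D2:**
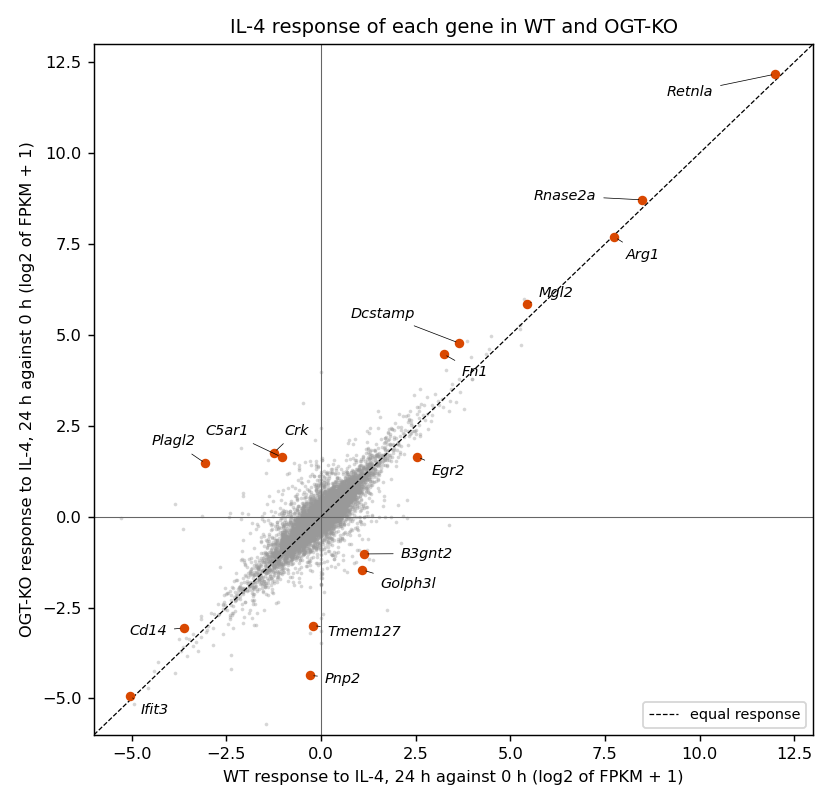
Log2 response to 24 h of IL-4 in the knockout (vertical axis) against WT (horizontal axis), with 1 point per gene for 12000 genes and the dashed line marking equal responses. Points follow the line with r 0.859, while Plagl2, Crk and C5ar1 have responses of opposite sign, and genes listed at 0, such as Rnase2a in WT at 0 h, are drawn at the value their pseudocount gives.

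The knockout was then compared with WT at 0 h, without IL-4. The apolipoprotein genes Apoc1 (chromosome 7, 19689481 to 19692660, − strand) and Apoc2 (chromosome 7, 19671579 to 19677941, − strand) were higher in the knockout. Apoc2 stood at 128 FPKM against 31.3 (log2 1.99) and Apoc1 at 18.2 against 3.79 (2.00). Nfe2l1, which encodes a transcription factor of proteasome genes (chromosome 11, 96817414 to 96829968, − strand), was at 30.6 against 8.56 (1.73), and the scavenger receptor gene Colec12 at 29.6 against 10.3 (1.43). Lower in the knockout were the complement receptor gene C5ar1 at 12.7 against 104 (−2.94), the adenosine deaminase gene Ada at 3.42 against 19.6 (−2.22), the macrophage elastase gene Mmp12 at 30.4 against 100.3 (−1.69), and Cd36, a receptor for oxidised lipids, at 189.5 against 459 (−1.27). Chil3 was at 182 against 334 (−0.87).

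Interferon-stimulated genes leaned higher in the knockout at 0 h. Of 35 measured, 33 had positive differences and 4 passed 2-fold (median 0.44, percentile 100), namely Cxcl10 (1.21), Cmpk2 (1.17), Xaf1 (1.16) and Rsad2 (1.05). MHC class II genes were positive in 9 of 10 cases with none past 2-fold (0.32, percentile 99.99), the exception being Ifi30 at −0.78. All 13 mitochondrially encoded genes had positive differences (0.29, percentile 99.99). Matrix and growth factor genes were 2-fold lower in 4 of 25 cases and higher in none (−0.28, percentile 0), with Plau (−1.23), Mmp9 (−1.21) and F13a1 (−1.19) beside Mmp12. NRF2 targets were negative in all but 2 of 15 (−0.29, percentile 0.01), with Gclm past 2-fold (−1.31). Gclm and Plau were low in the knockout at 0 h alone, with the other libraries close together. Lipid uptake and oxidation genes had a median of −0.20 (percentile 0.23), and cell cycle genes one of −0.33 (percentile 0), with none of 33 past 2-fold. All 11 neutrophil markers had negative differences (−0.66, percentile 0), among them Retnlg (−1.08) and S100a8 at 408 against 721 FPKM. The medians of monocyte (−0.47), stromal fibroblast (−0.51) and osteoclast markers (−0.64) also stood below random lists, though among their members only Mmp9 passed 2-fold. So did that of megakaryocyte markers, with Ppbp at 4.47 FPKM against 14.9 (−1.54). With a pseudocount of 5 the megakaryocyte list came within the central range, at percentile 2.65. The macrophage identity list was at 0.02. IL-4-induced genes had a median of −0.19 (percentile 0.97), with Egr2 at 3.83 against 9.69 FPKM (−1.15). That list came within the central range, at percentile 8.04, when no filter was applied.

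Further large differences at 0 h, all higher in the knockout, were Clmp (16.2 against 0.52 FPKM, 3.49), B3gnt2 (2.69) and the interferon-induced Ifit1bl1 (24.5 against 4.2 FPKM). Exons of B3gnt2 overlap those of Gm28048, which was at 37.8 FPKM in WT at 0 h and at most 0.02 in the other libraries. Zbtb22 (1.91) and Pttg1ip (1.90) were higher too, but were low in WT at 0 h alone, with the other libraries close together. Hist2h2aa1 was listed at 0 in WT and at 6.71 FPKM in the knockout. The transcription factor genes Plagl2 (−2.60) and Zfp62 (−2.22), Cipc (−1.93), Mamdc2 (−1.87), the chemokine receptor gene Ccr1 (−1.46) and the adaptor gene Crk (−1.63) were lower. In all, 101 genes were higher and 100 lower among 11479. With a pseudocount of 5 the counts were 23 and 20. Of 39 genes named by rule, 17 then came under 2-fold, namely Egr2, Cxcl10, Cmpk2, Xaf1, Rsad2, Gclm, Mmp9, F13a1, Retnlg, Mgea5, Arg2, Bid, Cx3cr1, Prg2, Rgs1, Vma21 and Zfx.

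At 24 h of IL-4 the same genotypes were compared. Egr2, which encodes a transcription factor of the IL-4 programme (chromosome 10, 67535475 to 67542188, + strand), stood at 14.1 FPKM in the knockout against 61.1 in WT (−2.04). The antioxidant gene Srxn1 was at 9.08 against 55.9 (−2.50), Ada (chromosome 2, 163726584 to 163750239, − strand) at 2.08 against 8.92 (−1.68), and the integrin gene Itgam at 31.1 against 66.7 (−1.07). Higher in the knockout were Colec12 (chromosome 18, 9707595 to 9882644, + strand) at 18.7 against 5.09 (1.69), Apoc2 at 23.2 against 6.64 (1.66), the lysozyme gene Lyz1 at 31.3 against 10.3 (1.52), and the coagulation factor gene F10 at 146 against 70.4 (1.04). Nfe2l1 was at 33.4 against 11.5 (1.46). The IL-4 markers Retnla (0.20), Arg1 (−0.13), Mrc1 (−0.28) and Chil3 (−0.58) were within 2-fold. Of 29 measured IL-4-induced genes, 28 were within 2-fold, the exception being Egr2 (median −0.10, percentile 10.9). With a filter at 5 FPKM the median of this list was −0.18, at percentile 0.10.

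MHC class II genes were again positive in 9 of 10 cases at 24 h (0.47, percentile 100), with Ifi30 at −0.73 and H2-Ab1 at 0.60. Ribosomal protein genes were positive in 3 of 36 cases (−0.28, percentile 0), and lysosome genes in 22 of 28 (0.09, percentile 99.7). In the knockout 24 h library alone, several structural and small RNA genes, chosen after their values were seen, were more than 2-fold higher. Gm23935 was at 205 FPKM against 57.7 to 69.9 in the other libraries, Mir6236 at 61.8 against 14.2 to 20.8, Rn7s1 at 10.2 against 2.54 to 2.80, and an annotated rRNA gene at 177 against 68.5 to 81.3. Among LXR targets and fatty acid synthesis genes, Apoc2, Apoc1 (1.31) and Scd1 (1.30) passed 2-fold (median 0.08, percentile 97.9). Cell cycle genes had a median of −0.24 (percentile 0.01). With a filter at 5 FPKM neither of these last lists stood apart, at percentiles 97.02 and 8.25. Interferon-stimulated genes were positive in 18 of 33 cases (0.04, percentile 96.6), and stood above random lists after rescaling (0.10, percentile 97.9) and with a pseudocount of 5 (0.03, percentile 98.1). Neutrophil markers were positive in 1 of 11 cases (−0.33, percentile 0.02).

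Among genes ranked by the naming rule, which leaves out predicted genes and small RNAs, the largest positive difference at 24 h was that of Pet117, listed at 1.2e-05 FPKM in WT and at 12.7 FPKM in the knockout. Others in that ranking were Tmem170b (2.38), Plagl2 (1.91), Zfp62 (1.79), Evi2 (1.77) and the cytokine signalling gene Socs6 (1.61). Pet117 and Tmem170b were low in WT at 24 h alone. Pnp2 was at 0.15 against 10.4 FPKM (−3.31). Of the 10 largest negative differences in that ranking, 6 were genes low in the knockout at 24 h alone, with the other libraries close together. These were Tmem127 (−2.77), Gcnt1 (−2.18), Emp1 (−1.75), Ttyh3 (−1.64), Ccdc115 (−1.62) and Sirpa (−1.63), which encodes the CD47 receptor and stood at 100.5 FPKM against 312. In all, 94 genes were higher and 70 lower among 11302. With a pseudocount of 5 the counts were 23 and 16, and 9 of 26 genes named by rule came under 2-fold, namely Mgea5, Ada, Ppbp, Itgam, Apoc1, Scd1, F10, Zfp62 and Rell1.

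Across 12000 genes the knockout differences at 0 h and 24 h had a Pearson r of 0.352, a Spearman rho of 0.443 and a slope of 0.338. Of the 201 genes past 2-fold at 0 h, 127 (63.2%) had the same sign at 24 h. Past 2-fold at both times were 12 genes that were higher and 13 that were lower, against 0.79 and 0.58 for independent choices. Another 13 genes were past 2-fold in opposite directions, as many as were lower at both times. Passing 2-fold at both times is thus not by itself a sign of a stable knockout difference. After their values were seen, these shared genes were singled out, among them Ppbp of the megakaryocyte marker list. Those higher were Apoc1, Apoc2, Nfe2l1, Colec12, Lyz1, Pcp4l1 (1.42 and 1.15), the fatty acid binding protein gene Fabp3 (1.38 and 1.02), Ldah (1.17 and 1.19) and 4 predicted genes. Those lower were Ada, Egr2, Mgea5, Ppbp (−1.54 and −1.19), Prss34 (−1.72 and −1.63), Scamp4 (−1.47 and −1.44), the glutathione transferase gene Gstp1 (−1.25 and −1.11), Vill (−1.17 and −1.03), the mitochondrial tRNA gene mt-Th (−1.24 and −1.09) and 4 predicted genes or segments. When the pseudocount was 5, of these 25 genes 6 of the 12 higher and 1 of the 13 lower stayed past 2-fold at both times, namely Apoc2, Nfe2l1, Colec12, Lyz1 and 3 predicted genes.

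**Figure D3:**
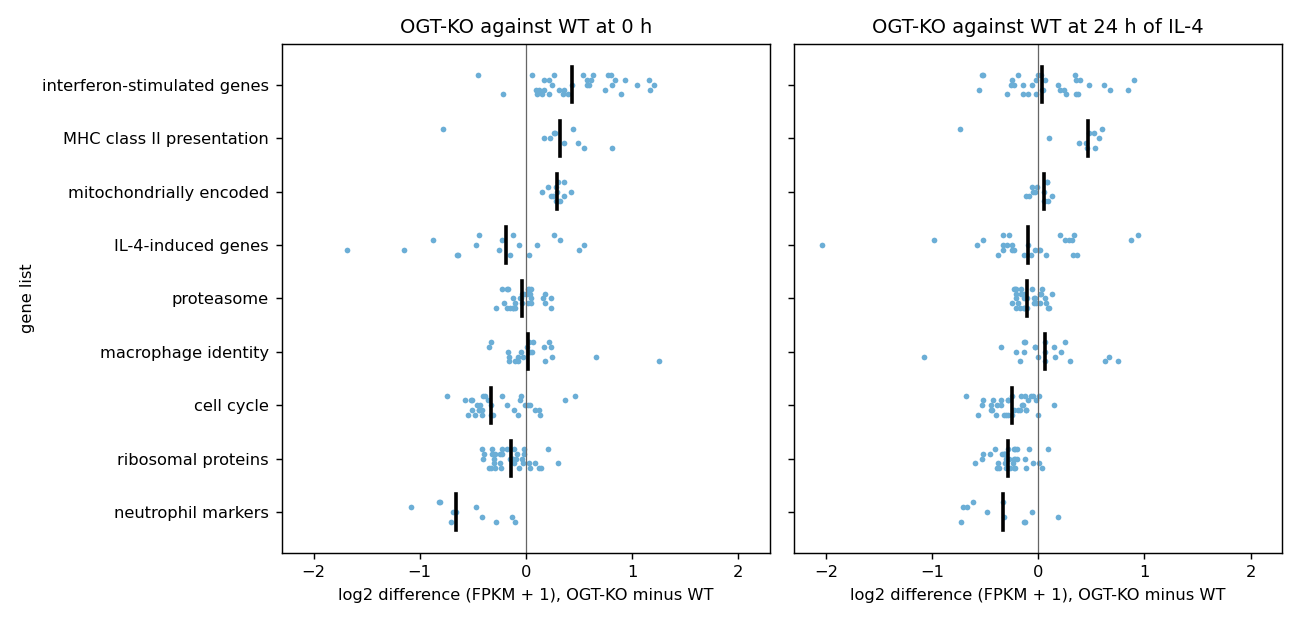
Log2 difference between knockout and WT of each kept member of selected fixed lists at 0 h and at 24 h of IL-4, with 1 point per gene and a bar at the list's median. The median of interferon-stimulated genes lies at 0.44 at 0 h and 0.04 at 24 h (0.51 and 0.10 after rescaling), that of MHC class II genes at 0.32 and 0.47, and that of neutrophil markers at −0.66 and −0.33.

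The last comparison asked which IL-4 responses differed in size, as the knockout response minus the WT response. The transglutaminase gene Tgm2 went from 24.4 to 79.0 FPKM in WT and from 26.3 to 39.5 in the knockout (difference −1.09). The chemokine gene Ccl22 went from 1.72 to 6.67 in WT and from 0.95 to 13.7 in the knockout (1.42). Fn1 reached 96.9 FPKM in WT and 189 in the knockout (1.24), and Dcstamp 37.6 and 58.3 (1.12). Mmp12, lower in the knockout at 0 h, reached 232 and 161 (1.17). Srxn1 went from 31.5 to 55.9 in WT and from 20.3 to 9.08 in the knockout (−1.89). Its list of NRF2 targets went the other way, with 13 of 17 differences positive (median 0.18, percentile 99.96) and Gclm at 1.30. The value of Gclm comes from the knockout at 0 h alone, at 2.47 FPKM against 6.47 to 7.59 in the other libraries.

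For each gene this difference equals its knockout difference at 24 h minus that at 0 h, so it holds no evidence beyond them. Interferon-stimulated genes, which leaned higher at 0 h, were lower in it, with 3 of 35 positive (median −0.35, percentile 0). Cxcl10 passed 2-fold (−1.27), at 8.52 FPKM in the knockout against 3.11 in WT at 0 h, and at 0.20 against 0.26 at 24 h. The NRF2, mitochondrially encoded, lipid uptake, neutrophil and monocyte lists of this comparison also stood apart at 0 h, in the opposite direction. Matrix and growth factor genes had a median of 0.27 (percentile 100), with 3 of 26 past 2-fold, and osteoclast and fused macrophage markers one of 0.44 (percentile 100). Between genotypes both medians were below random lists at 0 h (−0.28 and −0.64), and neither stood apart at 24 h (−0.07, percentile 26.5, and −0.08, percentile 34.02). Lipid uptake and oxidation genes were positive in 16 of 19 cases (0.18, percentile 99.97). All 13 mitochondrially encoded genes had negative differences (−0.24, percentile 0.07), and splicing regulators had a median of −0.13 (percentile 0.05). Neutrophil markers (0.20, percentile 99.8) and monocyte markers (0.29, percentile 99.7) stood above random lists in the same comparison. IL-4-induced genes did not stand apart (0.06, percentile 92.7), but did so at 0.09 with the libraries rescaled (percentile 98.9).

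Among genes ranked by the naming rule, at 5 FPKM or more and without predicted genes or small RNAs, the largest positive differences were those of Plagl2 (4.52), Pet117 (4.18), Zfp62 (4.01), Crk (3.01), Evi2 (2.69), C5ar1 (2.68) and the kinase gene Map2k7 (2.63). Pet117 was at 1.2e-05 FPKM in WT at 24 h, so its value and its place in this order depend on the pseudocount. Leaving out Hist2h2aa1, listed at 0 in WT at 0 h, the largest negative ones were Pnp2 (−4.08), Clmp (−2.89), Tmem127 (−2.78), Golph3l (−2.55), Rnf6 (−2.43), B3gnt2 (−2.17), Gcnt1 (−2.16) and the apoptosis gene Bid (−2.14). In all, 152 genes had a positive difference of at least 2-fold and 139 a negative one, among 12000. These values add the departures of all 4 libraries. With a pseudocount of 5 the counts were 36 and 36, and 7 of 32 genes named by rule came under 2-fold, namely Ccl22, Dcstamp, Cxcl10, Gclm, Scd1, Cx3cr1 and Siglecf.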

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

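Of the tests in this part, the one for genes with no exon overlap, those of the interferon-stimulated genes and those of genes low in a single library were chosen only after the result was seen.

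Some genes passed 2-fold in opposite directions between genotypes, and these differences were not tested, since each group held 1 library. The response to IL-4 was positive in the knockout and negative in WT for Plagl2 (difference of the responses 4.52), Zfp62 (4.01), Crk (3.01), Usf3 (2.96), C5ar1 (2.68) and Phc3 (2.64). It was negative in the knockout and positive in WT for Golph3l (−2.55), Rnf6 (−2.43) and B3gnt2 (−2.17). For Map2k7 the knockout differences at 0 h and 24 h had opposite signs (2.63). Exons of Map2k7 overlap those of Gm49320, which moved at least 2-fold the other way between WT at 0 h and WT at 24 h. Usf3 and Phc3 are named because they met the condition of opposite directions. A further 5 predicted or small RNA genes met it as well. In several of these genes WT at 0 h lay near the knockout at 24 h: Rnf6 was at 6.09 and 6.86 FPKM in those libraries, and at 16.0 and 16.7 in WT at 24 h and the knockout at 0 h.

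For the 14 genes with opposite responses, counting error of few fragments was argued against: 14 of 14 had a difference beyond 3 estimated counting errors, with C5ar1 at 38.9 and Plagl2 at 45.7. Selection from many genes weakens this for the small RNA genes, the lowest of which was at 3.67. Fragments divided differently between genes that share exon positions are argued against for the 8 genes with no such overlap in GENCODE M21. The release used by the authors is not given and may hold other overlaps. For the other 6 as a set this division cannot be told apart from a real difference: 42.9% of the 14 overlapped another gene against 34.3% of all kept genes. In 1 of them, B3gnt2, the overlapping gene moved the other way. That gene, Gm28048, was at 37.8 FPKM in WT at 0 h, where B3gnt2 was lowest at 4.34, and at most 0.02 in the other libraries. The opposite response of B3gnt2 can come from that division and is not read as a genotype difference. Transcript models of different length stay open too, with 42.9% of the 14 having models far enough apart against 54.1% of all genes, and a genotype difference in the response may also be the source, untested without replicates.

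Interferon-stimulated genes leaned higher in the knockout at 0 h, with a median log2 difference of 0.44 and most members within 2-fold. Scaling of the libraries was argued against, since rescaling left the median at 0.51. Fewer neutrophil-lineage cells in the knockout culture could raise genes of the remaining macrophages, and all 11 neutrophil markers had negative differences (median −0.66). That would raise macrophage genes alike, but the macrophage identity list had a median of 0.017. This argues against an even rise of macrophage genes only. Other differences in cell composition stay open, as all 5 marker lists with enough kept genes stood below random lists at 0 h. A difference between genotypes and a difference between these 2 cultures, such as their exposure to interferon, stay open and cannot be separated with 1 library each.

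Among 7336 genes at 5 FPKM or more, 36 protein-coding genes were at least 2-fold lower in 1 library than in each of the other 3, which lay within 1.5-fold of each other; this definition was set after the values were seen. They numbered 10 in WT at 0 h, 9 in WT at 24 h, 8 in the knockout at 0 h and 9 in the knockout at 24 h. An excess of such genes in knockout cells with IL-4 was argued against, since the knockout 24 h library held 1 time the mean of the other 3. Genes that differ by more than 1.5-fold among the other libraries, by genotype or with IL-4, cannot enter this set. A smaller IL-4 response in the knockout is thus not covered. The highest count over the lowest was 1.25, as departures of single libraries would give. Given how the set was defined, this evenness cannot show that such departures are unrelated to genotype or time. Genes higher in 1 library were uneven, at 5, 1, 6 and 8 in the same order, of which 3, 0, 3 and 1 were protein-coding. Sirpa, Tmem127, Gcnt1, Emp1, Ttyh3 and Ccdc115 belong to the 9 of the knockout at 24 h, so a biological loss in any 1 of them stays open and would need replicate cultures.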

How the results depend on the processing

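The counts restricted to protein-coding genes and to genes without exon overlap were chosen only after the data had been seen, and all other alternatives beforehand. Ogt kept its direction and size in all 6 settings between genotypes (log2 from −0.94 to −0.76 at 0 h and from −1.04 to −0.84 at 24 h). The r of the IL-4 responses ranged from 0.787 to 0.902, and that of the knockout differences from 0.264 to 0.421. Rescaling the libraries, keeping the highest entry per symbol and dropping the filter left all 10 counts within 1.5 times; without the filter the counts of the comparisons between 2 libraries cannot change, because a gene under 1 FPKM cannot reach 2-fold with a pseudocount of 1. Changes with a smaller or larger pseudocount follow from how those settings are built. Fewer genes also lower a count, but not always in proportion. At 0 h, 9846 of 11479 kept genes were protein-coding, against 57 of the 101 higher and 67 of the 100 lower. For the WT response these were 10037 of 11687 genes, 473 of 556 higher and 628 of 732 lower. Genes of other types were thus overrepresented among the genes past 2-fold between genotypes at 0 h. Counts are given as higher and lower for the WT response, the knockout response, the knockout difference at 0 h and at 24 h, and the difference of responses. With a pseudocount of 0.1 they were 845 and 1126, 963 and 1068, 202 and 236, 209 and 179, and 372 and 290. With a pseudocount of 5 they were 253 and 304, 272 and 320, 23 and 20, 23 and 16, and 36 and 36. With a filter at 5 FPKM the last 3 were 52 and 54, 55 and 38, and 77 and 64. For protein-coding genes they were 57 higher at 0 h, 59 and 40 at 24 h, and 86 and 74 for the difference. For genes without exon overlap they were 450 lower in the knockout response, 49 and 62, 51 and 39, and 87 and 68. Over the 5 comparisons, 85 list medians stood apart and 91 did not. Of those 85, 72 did so in every setting. IL-4-induced genes moved across the limit at 0 h without a filter (−0.085), at 24 h with a filter at 5 FPKM (−0.18), and in the difference without a filter (0.089) and after rescaling (0.091); the cause was not tested. The chemokine and receptor list reversed in the knockout response without a filter, from 0.43 to −0.039; the cause was not tested. Of 323 values past 2-fold of genes named by rule, 82 came under 2-fold with a pseudocount of 5, 5 after rescaling and 1 with a pseudocount of 0.1, and none reversed. The table holds 1 unit, so the alternative of a second unit was not run. Depth limits genes near 1 FPKM most, at an estimated 40.0 fragments for a transcript of 2 kb.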

Other observations

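The only test in this part, of Nfe2l1 and the proteasome, was chosen after the result was seen.

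Beyond the groups described so far, single lipid and amino acid genes differed between 0 h and 24 h of IL-4 in both genotypes, in both directions. The desaturase gene Scd2 was at 9.67 and 55.7 FPKM in WT and at 9.74 and 53.6 in the knockout (log2 2.41 and 2.35), and the lipase gene Lpl at 315 and 855 in WT and at 244 and 787 in the knockout (1.44 and 1.68). Lower with IL-4 in both were Apoc2 (−2.08 and −2.41), Mylip (−1.68 and −1.33) and Apoc1 (−1.29 and −1.99), while Fabp5 passed 2-fold in WT (−1.11) and not in the knockout (−0.78), a difference that was not tested. The LXR and fatty acid synthesis list had 4 members higher and 6 lower in WT (median 0.38), and 4 higher and 3 lower in the knockout (median 0.43). Lipid uptake and oxidation genes had a median of 0.20 in WT (percentile 80.1) and of 0.46 in the knockout (percentile 99.8). The arginine transporter gene Slc7a2 was at 0.38 and 20.8 in WT and at 0.59 and 21.03 in the knockout. Serine synthesis gene Psat1 (2.16 and 2.29) and glutamine transporter gene Slc1a5 (1.82 and 2.23) were higher in both, within an ATF4 list at percentiles 99.99 and 99.92. Glycolysis genes had medians of 0.64 and 0.66, with Pfkp at 2.11 and 2.39 and Pgk1 at 1.68 and 1.93. The IL-4 receptor gene Il4ra was at 34.4 and 15.6 FPKM in WT (−1.09) and at 32.6 and 16.5 in the knockout (−0.94), and Il13ra1 at 7.84 and 1.10 in WT and at 8.34 and 1.38 in the knockout. Ighm, a B cell gene, was at 119 and 9.05 FPKM in WT and at 152 and 14.1 in the knockout.

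Nfe2l1 was higher in the knockout at both times, and its protein is known to drive proteasome genes. A hypothesis was that proteasome subunit transcripts may rise with it. The proteasome list did not stand above random lists, at percentile 32.3 at 0 h and 6.72 at 24 h. Its medians were −0.04 and −0.11, and the first turned to 0.04 after rescaling. The result was negative.

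Xist was at 63.9, 72.6, 54.2 and 64.5 FPKM in WT at 0 h, WT at 24 h, the knockout at 0 h and the knockout at 24 h, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were listed at 0 in all 4 libraries. The predicted gene Gm27517 was at 0.16 and 0.17 FPKM in WT and at 29.3 and 31.4 in the knockout, at 0 h and 24 h. Gm47308, annotated as a microRNA, was at 52.6 and 54.2 in WT and at 0.24 and 0.01 in the knockout. The pseudogene Gm6977 was listed at 0 in the knockout at 24 h and at 71.7, 25.3 and 50.7 FPKM in WT at 0 h, WT at 24 h and the knockout at 0 h.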
